A study of Streptomyces clavuligerus with 2 samples.

How the data were processed

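RNA was measured in 2 libraries of Streptomyces clavuligerus mycelium, 1 from the wild-type strain ATCC27064 and 1 from the industrial strain F613-1. Per the labels' protocols, both strains were grown at 30 °C in liquid fermentation medium and harvested at 72 h. RNA was extracted after grinding under liquid nitrogen and treated with DNase before Illumina cDNA libraries were made. The aligner, the counting tool, the genome build, the treatment of reads that fit several places and the strandedness of the libraries are not given in the sources used here. Where genes overlap or resemble one another, reads of one cannot be told from reads of the other here. The protocols do not describe a step that removes ribosomal RNA.

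The deposited table held 7182 genes with a position, a strand and a length, and for each library a column of read counts and a column of RPKM, per the file headers. The counts were deposited as raw whole numbers per gene. The RPKM (reads normalised to gene length and library total) deposited by the authors equalled the count divided by gene length and by the column total, with a largest deviation of 0.000504% in F613-1 and 0.000485% in ATCC27064. The counts were therefore used throughout and the RPKM served as an alternative. The gene length of every row equalled the span of its position. Of the 7182 features, 7125 had a length that was a multiple of 3 and 57 did not. Positions are 1-based as deposited, on replicons named Chr1 (the chromosome) and pSCL1, pSCL2, pSCL3 and pSCL4 (plasmids). All counted features refer to this one set of gene models, so genes carried by F613-1 alone are not analysed here.

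The gene identifiers of the table are locus tags that matched 0 of the 7015 entries of the available gene name table, which belongs to another assembly of the same species. The file pairs no identifier with a gene name. Before the data were examined, 30 gene lists (antibiotic pathways, regulators, primary metabolism, ribosomal proteins, mobile elements and others) had been fixed by gene name and product. None of them could be filled, so no pathway is reported, and the comparison rests on replicons, stretches of neighbouring genes and single features given by position. For the same reason a gene is described only by its position and length, and nothing is said of its function.

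The total count was 13147639 in ATCC27064 and 11335398 in F613-1. Counts were divided by these totals and multiplied by 1000000 to give CPM, and the ratio of F613-1 to ATCC27064 was taken as log2 of CPM with a pseudocount of 1 CPM. Such a log2 ratio understates the change of weakly expressed genes. A gene was counted when it reached 50 reads in the higher library, which left 6075 genes. Genes at least 4-fold apart were counted as higher or lower. With 1 library per strain there is no replicate error and no test between strains, and no p-value is given. An exact 95% interval (Clopper-Pearson on the share of the reads of both libraries that came from F613-1) was computed for each ratio of CPM and is printed for some of them. These intervals cover counting error only, because sequenced fragments are not independent molecules and no culture was repeated. A count of 0 allows up to 3 reads, which is 0.228 CPM in ATCC27064 and 0.265 CPM in F613-1. Where a gene had 0 reads, the fold was computed against these 3 reads in that library and is a lower bound. This bound is one-sided, and the low end of the two-sided 95% interval of such a gene lies below it. For each replicon the median log2 ratio was set against the medians of 10000 random gene sets of the same size, matched on mean expression in 20 bins.

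The following steps were chosen after the data had been seen. Stretches of genes without F613-1 reads were found with a 2-state Viterbi path along each replicon. Its input was whether each gene with at least 50 reads in ATCC27064 had at most 3 reads in F613-1, with probabilities of 0.95 inside a block and 0.01 outside and a switch probability of 0.001 per gene. Runs of at least 3 neighbouring genes that all lay beyond 4-fold in one direction, and runs of at least 8 beyond 2-fold, were listed outside those blocks. Their numbers were compared with 1000 shuffles of gene order within each replicon. The CPM ratios of runs were recomputed without their 1 or 2 most abundant genes, and those of blocks without genes above 10% of their ATCC27064 level.

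The rule for single features, fixed before the data were examined, took the 10 largest and the 10 smallest ratios, the 5 highest genes of each strain and the 5 highest genes of each strain that were at 0 in the other. The features with the smallest ratios outside the blocks were added afterwards. Identifiers are printed for at most 2 features that were higher and 2 that were lower.

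On simulated counts for the 7182 genes, the 4-fold rule called 50 of 50 genes raised 8-fold and 50 of 50 lowered 8-fold, 0 of the 100 genes changed 2-fold and 0 of 6982 unchanged genes. On 5291 simulated chromosomal genes with 2 silenced stretches, the path found both blocks, with 319 of 319 informative genes and 0 false ones. These simulations contain counting error alone. Alternatives covered the pseudocount, the level filter, the scaling (TMM of edgeR 4.0.16, DESeq2 1.42.0 size factors, upper quartile, median centring, chromosome total), the most abundant genes, genes at 0, the RPKM and the block settings. edgeR and DESeq2 supplied scaling factors only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.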

Results

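The transcriptomes of 2 strains of Streptomyces clavuligerus, a soil actinomycete that makes the beta-lactamase inhibitor clavulanic acid and the antibiotic cephamycin C, were compared after 72 h of fermentation. ATCC27064 is the wild-type strain and F613-1 is an industrial strain. The series title concerns the compact genome of a clavulanic acid producer and its reservoirs of horizontal transfer, so the comparison asks how the industrial strain differs from the wild type in the transcription of its chromosome and plasmids. Each strain was represented by 1 library, with 13147639 counted reads for ATCC27064 and 11335398 for F613-1. The median gene had 367 reads in ATCC27064 and 217 in F613-1. Of the 7182 genes, 35 had no read in ATCC27064 and 1239 had none in F613-1. The 10 most abundant genes took 8.89% of the reads in ATCC27064 and 13.2% in F613-1.

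Large parts of the plasmids gave almost no reads in F613-1, while the chromosome was transcribed at similar levels in both strains. Plasmid pSCL3 yielded 113271 reads over 351 genes in ATCC27064 and 70 reads in F613-1, a CPM 1395-fold lower (95% counting interval 1104 to 1790). A single gene held 24 of the 70 reads. On pSCL4, the megaplasmid, 807 of 1390 genes had no read in F613-1, against 12 in ATCC27064. On pSCL2, 85 of 142 genes were at 0 in F613-1 and 2 in ATCC27064. Only 11 of the 5291 chromosomal genes were at 0 in F613-1 and 13 in ATCC27064. The 8 annotated genes of pSCL1 had no reads in either library, so a difference on pSCL1 was not detectable.

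Among the 6075 genes with at least 50 reads in 1 library, 68 were at least 4-fold higher in F613-1 and 1045 at least 4-fold lower. A further group of 4228 genes, 69.6%, stayed within 2-fold. The lower genes comprised 155 of 4763 on the chromosome (3.25%), 83 of 115 on pSCL2 (72.2%), 243 of 244 on pSCL3 and 564 of 953 on pSCL4 (59.2%). The higher genes comprised 49 on the chromosome, 2 on pSCL2, 17 on pSCL4 and 0 on pSCL3. The count of lower genes was 414 with a pseudocount of 10 CPM, 597 with a level filter of 250 reads and 288 when genes at 0 in either strain were left out.

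The median log2 ratio was -0.04 on the chromosome and -2.82 on pSCL4, a difference of -2.79. It was -3.65 on pSCL2 and -3.92 on pSCL3. In 10000 expression-matched random gene sets the median ranged from -0.42 to -0.15 for sets of the size of pSCL4, so pSCL4 lay below every set drawn. The medians of pSCL2 and pSCL3 were likewise below all of their 10000 sets. The chromosome, at -0.04, lay above all of its own sets, which ranged from -0.16 to -0.12. The sets were drawn gene by gene from all counted genes, those of the replicon included. They ignore that unread genes lie next to each other, so a place beyond every set describes a replicon and is not separate evidence. The size of the difference between pSCL4 and the chromosome depended on the settings. It was -4.30 with a level filter of 250 reads and -1.49 without a level filter. A pseudocount of 0.1 CPM gave -5.74 and one of 10 CPM gave -0.81. Leaving out genes at 0 gave -0.38, but that setting removes genes without F613-1 reads by construction.

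**Figure D1:**
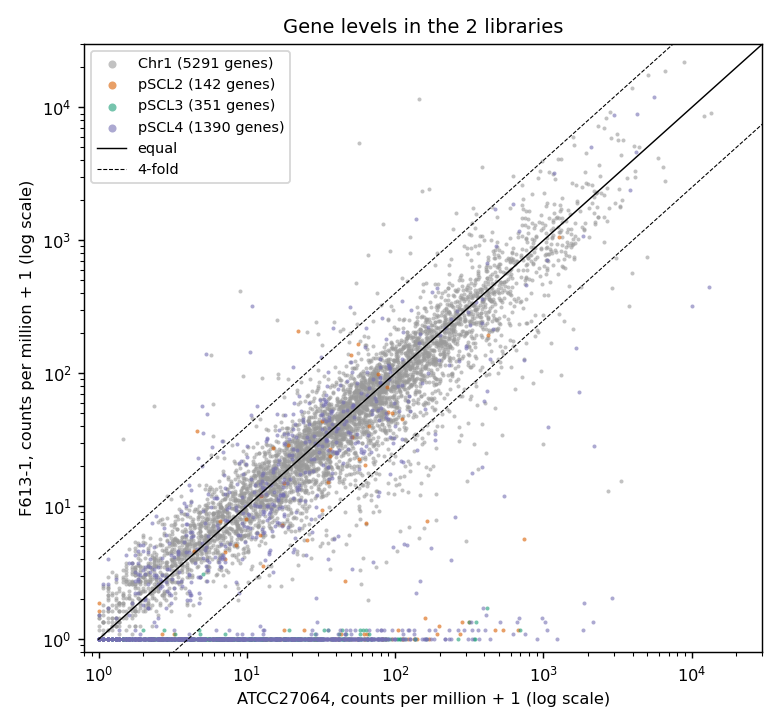
CPM plus 1 of each gene in ATCC27064 (horizontal axis) and F613-1 (vertical axis), both on log scales, coloured by replicon, with the solid line at equality and dashed lines at 4-fold. Chromosomal genes follow the line of equality, while genes of pSCL2, pSCL3 and pSCL4 also fill the bottom edge, where F613-1 had no or very few reads.

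The unread genes formed 4 continuous blocks that together spanned 1667 kb and 1309 genes. The first covered pSCL2 from 872 to 106162, with 102 genes and 72672 reads in ATCC27064 against 35 in F613-1 (1790-fold lower CPM, interval 1287 to 2570). The second covered pSCL3 from 958 to 440878, nearly the whole plasmid as annotated, with 349 genes, and was 2121-fold lower (interval 1590 to 2897) without the gene that held 24 reads. The third ran from 367 to 744799 on pSCL4, with 588 genes and 331940 reads against 197 (1453-fold lower, interval 1263 to 1679). One gene, with 121 reads in ATCC27064, held 87 of the 197, and without it the block was 2601-fold lower (interval 2158 to 3164). The fourth ran from 1408634 to 1786143 on pSCL4, with 270 genes and 167509 reads against 41 (3522-fold lower, interval 2596 to 4909). Of the 847 genes in these blocks with at least 50 reads in ATCC27064, 827 (97.6%) had at most 3 reads in F613-1. Outside the blocks the same was true of 2 of 5098 genes. The blocks were drawn from this same property, so the contrast describes them and is not separate evidence. In ATCC27064 the blocks held 685330 reads, 5.21% of the library, and in F613-1 343 reads.

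The edges of the blocks were resolved to between 0 and 4 intervening weakly expressed genes. On pSCL2 the last unread gene ended at 106162 with 254 reads in ATCC27064 and 0 in F613-1, and the next gene began at 106213 with 649 and 1541 reads. On pSCL4 the left edge lay between 744799 and 748856, a stretch that held 4 weakly expressed genes. The right edge lay between 1407039, the end of a gene with 58 and 550 reads, and 1408634, the start of a gene with 75 and 0 reads, with 1 weakly expressed gene between them.

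The 10 genes with the smallest ratios all lay in the pSCL4 blocks, and some of them were among the well expressed genes of ATCC27064. SCN_RS37750 (pSCL4, 1641152 to 1642555) had 28530 reads in ATCC27064 and 4 in F613-1, a log2 ratio of -10.65. That value depends on the pseudocount, with -12.23 at 0.1 CPM and -7.72 at 10 CPM. With so few F613-1 reads, the order of these genes partly follows their ATCC27064 level. A gene of 2511 bases at 1575547 to 1578057 had 24363 and 2 reads. Another of 6996 bases at 538960 to 545955 had 16334 and 0 reads, which is at least 4694-fold lower. A neighbourhood from 619016 to 627310 contributed several further genes, among them one with 11817 reads against 0 (at least 3396-fold lower) and one with 38415 against 12. The highest gene of pSCL3 without F613-1 reads, at 129825 to 130646, had 4560 reads in ATCC27064 (at least 1310-fold lower). No gene with at least 50 reads in F613-1 was at 0 in ATCC27064. Genes carried by F613-1 alone were not among the counted features, so this count cannot show that losses ran one way.

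Between the blocks, pSCL4 from 748856 to 1407039 was transcribed in both strains. This stretch of 658 kb held 520 genes, 1081049 reads in ATCC27064 and 842546 in F613-1. Its median log2 ratio was -0.14, a difference of -0.10 from the chromosome. Among 428 counted genes, 17 were at least 4-fold higher in F613-1, 40 at least 4-fold lower and 272 within 2-fold. This median pools parts that differ in direction: left of 1100000, a split chosen from the data, the median was -0.65, and right of it 0.54. The remaining stretch of pSCL2, from 106213 to 148725 with 40 genes, had a median of -0.72 over 37 counted genes. Series of as many consecutive counted chromosomal genes had medians from -1.45 to 1.46, so this median lay within their range.

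**Figure D2:**
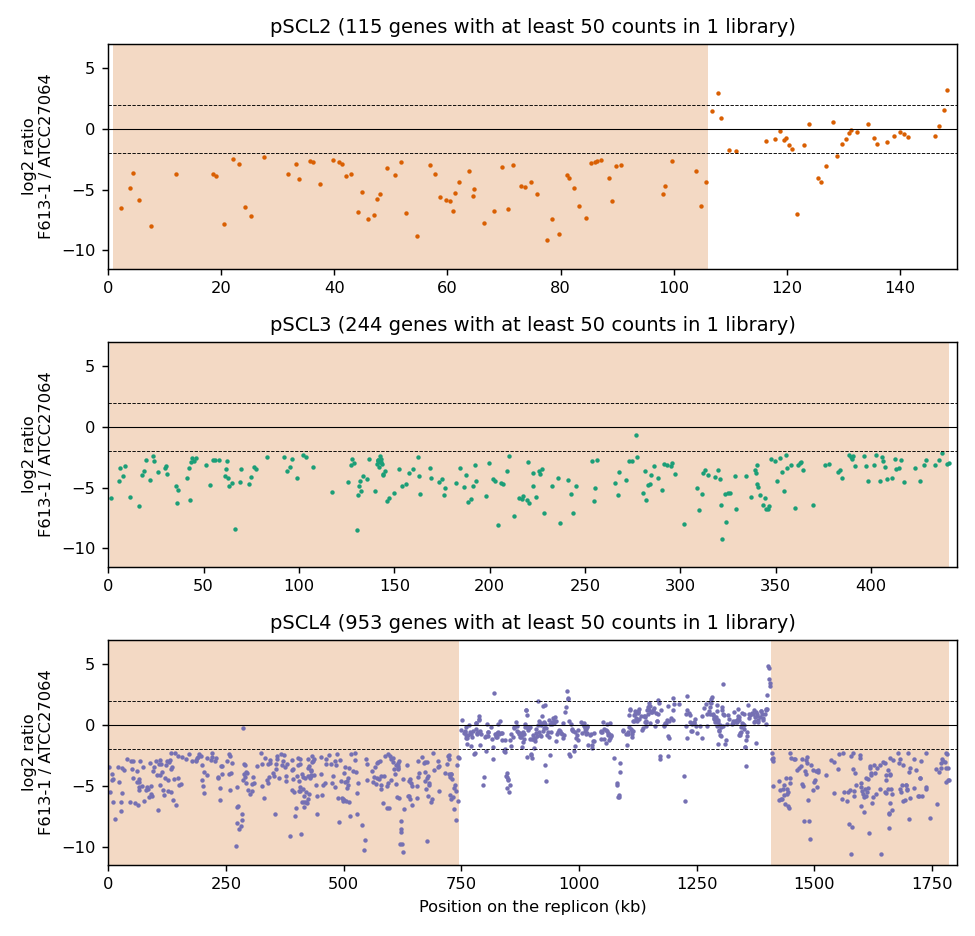
Log2 ratio of F613-1 to ATCC27064 (vertical axis) of each gene with at least 50 reads in 1 library, by position in kb on pSCL2, pSCL3 and pSCL4, with dashed lines at 4-fold and the 4 unread blocks shaded. Unshaded parts are pSCL2 beyond 106213 and pSCL4 from 748856 to 1407039, where median log2 ratios were -0.72 and -0.14.

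Outside the blocks the strains differed at fewer genes, and lower genes outnumbered higher ones. Of 5228 counted genes, 200 were at least 4-fold lower in F613-1 and 68 at least 4-fold higher, with a median log2 ratio of -0.04, and 80.8% lay within 2-fold. The balance depended on scaling, with 156 lower and 95 higher genes under upper quartile scaling. With a counting interval wholly beyond 4-fold, 173 were lower and 55 higher. Spearman's rank correlation of the counts was 0.92 across the 5873 genes outside the blocks and 0.93 across the chromosome, a relation across genes, which are not independent replicates. Over all genes it was 0.81.

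Many neighbouring genes were higher in F613-1 on the chromosome from 4834075 to 4886392, a stretch drawn after the values were seen. It joins 2 series of at least 8 neighbours that were all at least 2-fold higher, and the genes between them. Of its 31 genes, 28 were at least 2-fold higher in F613-1, 3 of them at least 4-fold, and none was 2-fold lower. Together they took 4.16% of the reads in ATCC27064 and 11.8% in F613-1, a CPM 2.83-fold higher (interval 2.82 to 2.84). The most abundant gene of the F613-1 library lay here, at 4853199 to 4854920 (1722 bases), with 8880 CPM in ATCC27064 and 22100 CPM in F613-1, 2.49-fold higher. A gene at 4849548 to 4850525 had 3981 CPM in ATCC27064 and 14066 in F613-1, 3.53-fold higher. The longest gene of the stretch had 11346 bases. Outside the blocks, 7 series of at least 8 neighbours lay beyond 2-fold, and the 2 that were higher in F613-1 lay here, 1 of 11 genes at 4834075 to 4847895 and 1 of 10 genes at 4872570 to 4886392.

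Single genes differed by more. SCN_RS06875 (Chr1, 1714020 to 1715042) had 55.8 CPM in ATCC27064 and 5354 in F613-1, 96.0-fold higher (interval 89.3 to 103). SCN_RS21155 (Chr1, 5051154 to 5053199) had 144 and 11627 CPM, 80.7-fold higher (interval 77.1 to 84.5). A gene of 1281 bases at 162513 to 163793 was 51.9-fold higher (interval 42.7 to 63.5), from 105 to 4695 reads. A pair of neighbours at 5216796 to 5217768 had 6 and 18 reads in ATCC27064 and 352 and 631 in F613-1. The remaining genes among the 10 largest ratios were a pair on pSCL4 at 1400460 to 1403312, 32.4-fold and 32.5-fold higher, and chromosomal genes at 699452, 1698836 and 1985803, with log2 ratios of 4.58, 4.02 and 3.96.

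Genes beyond 4-fold lay next to each other more often than shuffled gene orders gave. Outside the blocks there were 7 runs of at least 3 neighbouring genes that were all higher in F613-1, with 25 genes, and 14 runs that were all lower, with 74 genes. In 1000 shuffles the highest numbers were 1 and 3. The higher run with the most genes, 6, adjoined the right block of pSCL4 at 1399444 to 1407039 and had 13.4-fold higher CPM (interval 12.5 to 14.3). This run was 10.2-fold higher without its most abundant gene and 17.5-fold without the 2 most abundant. Chromosomal runs of higher genes lay at 698682 to 701954 (3 genes, 16.0-fold), 5262456 to 5267304 (3 genes, 9.85-fold, from 490 to 4825 CPM), 5216796 to 5222185 (4 genes, 8.12-fold), 212325 to 214904 (3 genes, 4.92-fold) and 1593899 to 1596249 (3 genes, 4.64-fold). In the same order, they were 11.5-fold, 7.41-fold, 17.6-fold, 5.19-fold and 4.13-fold higher without the most abundant gene of each. The last run, on pSCL4 at 973891 to 978070, was 5.89-fold higher, and 6.94-fold without its most abundant gene.

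The chromosomal run with the lowest ratio comprised 9 genes at 6186016 to 6197754, 7 on the minus and 2 on the plus strand, with 92912 reads in ATCC27064 and 620 in F613-1. Their summed CPM was 129-fold lower (interval 119 to 140), a value carried by 2 genes with 79639 of the reads in ATCC27064. Without these 2 it was 35.8-fold lower (interval 32.0 to 40.1), and the median log2 ratio of the 9 genes was -4.65. SCN_RS25710 (Chr1, 6196690 to 6197754) had the lowest ratio within it, with 3342 and 14.5 CPM, 231-fold lower (interval 198 to 271), and its neighbour at 6195152 to 6196624 was 226-fold lower. The longest run held 12 genes on the plus strand at 6076022 to 6089440 and was 7.77-fold lower (interval 7.44 to 8.13). Further runs lay at 2193854 to 2201731 (7 genes, 17.4-fold lower) and 2004064 to 2007202 (3 genes, 25-fold lower, 13.3-fold without the most abundant gene and 10.2-fold without the 2 most abundant). A run at 6167862 to 6171893 (5 genes) was 4.95-fold lower. The remaining 6 chromosomal runs of lower genes held 3 or 4 genes each and were 5.13-fold to 11.6-fold lower. Of these, the run at 6595176 to 6608282 went from 10.9-fold to 6.97-fold without its most abundant gene, and the run at 2988068 to 2993393 from 11.6-fold to 15.1-fold without 1 and 7.61-fold without 2 genes. Of the 460 counted genes beyond 6000000, a cut chosen after the values were seen, 44 (9.57%) were at least 4-fold lower and 1 was at least 4-fold higher. The 44 include the genes of the runs named above in this part. They were not spread evenly, with 38 of 309 counted genes (12.3%) up to 6500000 and 6 of 151 (3.97%) beyond it.

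The transcribed part of the plasmids held 3 runs of lower genes. On pSCL4, 8 genes on the minus strand at 844025 to 852996 were 30.2-fold lower (interval 29.4 to 31.0) and 8 genes at 1069676 to 1088642 were 28.0-fold lower (interval 27.2 to 28.9), or 18.6-fold without the most abundant gene and 13.7-fold (interval 12.8 to 14.7) without the 2 most abundant. Each contained one of the 5 most abundant genes of ATCC27064. The gene at 852496 to 852996 (501 bases) had 13143 CPM in ATCC27064 and 441 CPM in F613-1, and the gene at 1080777 to 1082699 (1923 bases) had 10002 and 320 CPM. A run of 3 genes on pSCL2 at 125455 to 127066 was 18.0-fold lower. The most reduced single gene of transcribed plasmid sequence lay on pSCL2 at 121360 to 122448, with 9726 and 53 reads. One chromosomal gene with at least 50 reads in ATCC27064, at 2058579 to 2058812 (234 bases), had 325 reads there and 0 in F613-1, which is at least 93.4-fold lower. It was singled out after its values were seen.

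**Figure D3:**
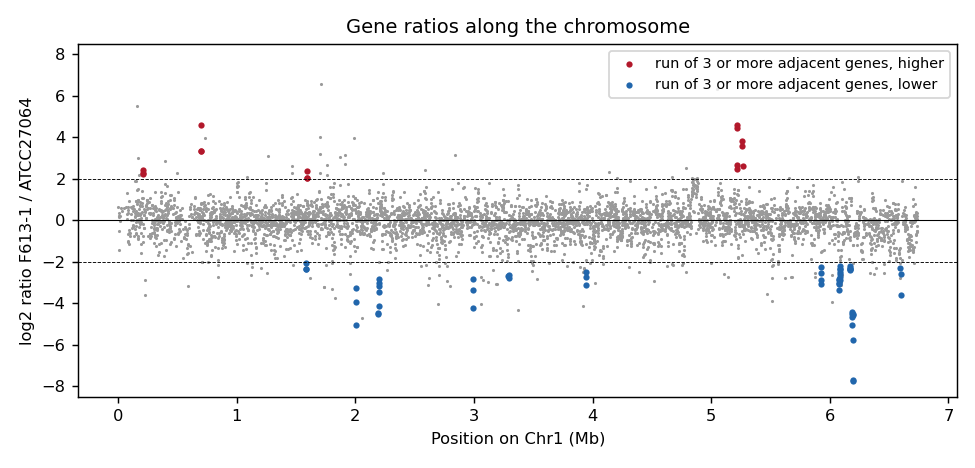
Log2 ratio of F613-1 to ATCC27064 (vertical axis) by position in Mb on Chr1 for the 4763 genes with at least 50 reads in 1 library, with dashed lines at 4-fold. Genes in runs of 3 or more adjacent genes beyond 4-fold are coloured, the lowest of them at 6186016 to 6197754.

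The other most abundant genes differed less. The top gene of ATCC27064, at 431797 to 433677 on the chromosome, had 13538 CPM there and 9086 in F613-1, 1.49-fold lower. A gene at 5801695 to 5804481 had 12151 and 8624 CPM, 1.41-fold lower. In F613-1 the second most abundant gene, at 3368594 to 3370372, was 2.87-fold higher than in ATCC27064. A feature of 400 bases at 1821190 to 1821589 was 3.50-fold higher, and its length is not a multiple of 3. On pSCL4 the gene at 1152611 to 1154278 was 2.14-fold higher, at 5602 and 11998 CPM. These differences exceed the counting error of the libraries, but with 1 culture sampled per strain they could not be set against variation between cultures.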

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

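The 8 alternatives for scaling, pseudocount, level filter, abundant genes and genes at 0 were fixed before the data were examined, and the other settings were chosen afterwards. The 68 higher genes stayed within 1.5 times under every setting run, from 48 with a pseudocount of 10 CPM to 95 with upper quartile scaling. The 1045 lower genes became 414 with a pseudocount of 10 CPM, 597 with a level of 250 reads and 288 without genes at 0 in either strain; this last setting removes genes of the unread blocks by construction, and lower genes then made up 80.9% of the calls instead of 93.9%. Outside the blocks the 200 lower genes became 121 with a pseudocount of 10 CPM, and lower genes made up 62.2% of the calls under upper quartile scaling and 67.2% after centring on all counted genes (166 lower, 81 higher) instead of 74.6%. The difference in median log2 ratio between pSCL4 and the chromosome, -2.79, kept its sign and was -5.74 with a pseudocount of 0.1 CPM, -0.81 with 10 CPM, -1.49 without a level filter, -4.30 at 250 reads, -2.95 without the 10 most abundant genes and -0.38 without genes at 0. Scaling moved the median of all counted genes from -0.17 to 0 by centring and to 0.07 by the upper quartile, and by under 0.1 with TMM, DESeq2 size factors or the chromosome total. The blocks held from 1289 to 1320 genes under 6 other settings, and a switch probability of 0.05 divided them into 7 instead of 4. At 3-fold instead of 4-fold there were 13 runs of higher and 22 of lower genes. Of 753 recomputed ratios of 59 single features, 586 stayed within their counting interval, 167 left it and 0 changed sign. Leaving out the most abundant gene moved the CPM ratio of 18 of 21 runs beyond its counting interval and reversed 0. Results planned for 30 named gene lists were not run because no identifier had a name. Leaving out replicates was not possible with 1 library per strain. No paired analysis was possible because each strain has a single library. Depth limits weak genes most, since 3 reads are 0.265 CPM in F613-1, and the missing replicates limit every ratio.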

Other observations

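The tests of the thinned depth and of the sources of the stray reads apart from the 2 set-aside genes were specified before their results were seen; the other tests of this part were chosen after the result had been seen. The transcribed stretch of pSCL4 was not uniform along its length. Left of position 1100000, a split chosen from the data, 228 counted genes had a median log2 ratio of -0.65 (95% order-statistic interval over genes -0.72 to -0.54), with 71 genes at least 2-fold lower and 11 at least 2-fold higher in F613-1. Right of it, 200 genes had a median of 0.54 (interval 0.37 to 0.75), with 17 lower and 57 higher. Series of as many consecutive counted chromosomal genes had medians from -0.49 to 0.24 and from -0.53 to 0.24, so each part lay outside its range.

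Genes beyond 6000000 on the chromosome had a median of -0.36 over 460 genes, near the lowest median (-0.37) of chromosomal series of as many genes, which include this one.

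The 4 blocks of unread plasmid genes in F613-1 are a pattern to follow up. The lower depth of F613-1 is argued against, because 391 chromosomal genes with 50 to 100 reads in ATCC27064 had a median of 70 reads in F613-1 and none had 3 or fewer, while 200 block genes of that level had a median of 0. Sequence divergence spread over the genome is also argued against, since 0.0215% of informative chromosomal genes had at most 3 reads. A candidate explanation is that F613-1 lacks the DNA of these blocks. It would leave no block gene above 10% of its ATCC27064 level, and 2 of 847 informative genes exceeded that. This count does not decide the question. The blocks were drawn from genes with at most 3 F613-1 reads, which lie below 10% by construction, so the low count is not separate evidence. Divergence or absence of transcription limited to the blocks cannot be told apart from missing DNA, because RNA counts on one set of gene models are the only data used here.

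The stray F613-1 reads within the blocks may be reads or RNA carried over from the ATCC27064 library. Leaving out the 2 genes with the most reads for their level, 232 reads remained in 99 of 1307 genes, 3.39 per 10000 ATCC27064 reads, and 2.45 to 4.82 per 10000 in the single blocks. These counts followed the ATCC27064 counts better than gene length, with a log-likelihood difference of 275. The 2 genes left out had many F613-1 reads for their ATCC27064 level, so leaving them out favoured this outcome. The comparison with gene length cannot tell carry-over from weak transcription of the blocks in F613-1, which could also follow the ATCC27064 levels. The 10% of genes highest in ATCC27064 held 65.5% of the 232 reads, against 71.3% of the ATCC27064 reads and 17.0% of the length. For these reads, this argues against placement in proportion to length. The 2 other genes lay at 276044 to 277045 on pSCL3 and 285271 to 286146 on pSCL4. They were picked for exceeding 10% of their ATCC27064 level, so an excess over the rate of the other genes followed from the choice. Their 111 reads, where that rate gives 0.0589, are more than carry-over at that rate accounts for. Reads shared with a similar gene elsewhere were not tested, as no sequence was used.

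Outside the blocks, 200 genes were at least 4-fold lower and 68 at least 4-fold higher, a ratio of 2.94. Counting noise from unequal depth is argued against as the whole cause, since thinning ATCC27064 to the F613-1 total left a ratio of 2.99. CPM already divides by the totals, so thinning could change little else. The part that scaling plays stays open: upper quartile scaling gave 156 lower and 95 higher genes, a ratio of 1.64 and the lowest of the scalings run, and centring outside the blocks (193 and 69) shifts ratios by too little, 0.04, to decide. Of the 268 calls, 99 lay in 21 runs of neighbouring genes, against at most 1 higher and 3 lower run in shuffled orders. This argues against random placement for those runs. The shuffles treat neighbouring genes as independent, so they cannot tell why neighbours changed together. A strain difference stays open as an untested biological explanation, as does variation between single cultures, because each strain has 1 library. Loss of reads where F613-1 genes diverge from the one set of gene models was not tested for this pattern either.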
